A study of Mus musculus with 2 samples.

How the data were processed

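Gene expression was measured on 2 microarrays, 1 for mice given phosphate-buffered saline (PBS) and 1 for mice given bortezomib. UM-PEL-1 is a line of primary effusion lymphoma, a B-lineage lymphoma of body cavities, that was passed in mice and not grown in culture. Per the labels' protocols, immunodeficient NOD/SCID mice carried the cells in the peritoneal cavity for 3 days before treatment. Each mouse then received 1 injection of PBS or of bortezomib at 0.3 mg/kg, and cells were taken after 24 hours. Bortezomib is a proteasome inhibitor used against myeloma and some lymphomas. RNA from the 3 mice of an arm was pooled before labelling, amplified with NuGEN whole-transcriptome reagents and labelled with biotin, per the labels. The spread between mice is therefore not in the data, and the comparison has 1 pool per arm.

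The deposited table holds log2 expression values for 28869 probe sets, per the values themselves, which lie between 2.70 and 14.0. Partek and GCRMA are named in the submitters' processing notes, without versions, order or settings. GCRMA is a routine that subtracts background by probe sequence, normalizes the arrays and summarises the probes of a set. The steps the authors took beyond these names are not given in the sources used here. The medians were 4.56 on the PBS array and 4.66 on the bortezomib array, and the upper quartiles were 6.45 and 6.22, so the final distributions were not identical. Scanner intensities, detection calls and probe-level values were not used here. The sample labels give the mouse as organism, whereas the platform annotation lists human genes. All values are therefore read as human transcripts, and hybridisation of RNA from mouse host cells cannot be separated from them.

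Probe sets were named through the platform annotation, which gave 1 gene symbol for 19310 probe sets, several for 1752 and none for 7807. Only probe sets with 1 symbol were named, and where a gene had several, the one with the highest mean level was used. XIST and genes of the Y chromosome were left out, which left 18344 genes. No coordinates are given, because the platform annotation used here holds none. The mouse gene table supplied beside it was not used.

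From these values the difference bortezomib minus PBS was computed per gene on the log2 scale as deposited. With 1 array per arm there is no residual spread, so no p-value, standard error or confidence interval over samples was computed. The number of arrays limits the precision. Genes were counted where the higher of the 2 values reached 4.61, the median of all values of both arrays (11222 genes), and where the difference was at least 2-fold. That level is a rank on these arrays and not a detection call, so a fold that starts from a value below it may be understated. As a guide to scatter between probe sets, the differences given by different probe sets of one gene were compared. Over 373 genes with such probe sets past the level filter, their SD was 0.44 on the log2 scale. Of 98 of these genes with at least 1 probe set changed 2-fold, 84 had all probe sets differing in the same direction. On the arrays, 826 probe sets held the same 2 values as another, and within a gene such copies were counted once. Probe sets that overlap in part were not looked for, so the SD may be too low and the agreement too high. This scatter covers probes only, and not the animals, the pooling or the labelling.

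Gene lists (31) for pathways and cell types were fixed before the data were examined, as were the level filter, the thresholds, the alternatives and the rule for named genes. For each list the median difference was set against 10000 random lists of the same size, drawn from other named genes and matched on deciles of the mean level of both arrays. A list is said to stand apart where its median lay below percentile 0.5 or above percentile 99.5 of those random lists. By chance, 0.31 of the 31 lists would do so if genes varied independently. Genes of a pathway do not, so a percentile describes these 2 arrays and is not a test of the treatment. Genes named are the 15 with the highest and the 15 with the lowest differences past the level filter, leaving out symbols without a curated name, immunoglobulin and T cell receptor segments. For each list up to 4 members were named with the largest differences in the direction of its median, and the largest in the other direction. A fixed set of genes such as PSMB5, MYC and CDKN1A was always named. The genes behind a 2-fold count of 5 or fewer were named too, and those that the rule does not give were chosen after their values were seen. They are HSPA4L, GCLM, TNFRSF10A, APAF1, H3C10 and IFIT5, and in the closing section SNORD4B, SNORD13P2, TUBA1C, TUBD1, GARS1, FARSA and SLC3A2. HSPA1A and HSPA1B share their probe sets and are given no value.

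The calculation was tested on simulated data for the 18344 genes, with the level-dependent spread of the real differences. Of 50 genes given a rise of 1.5 on the log2 scale, 74% were counted at 2-fold, and 86% of 50 given a fall of the same size. All of those changed by 3 were counted (100%), and 8.30% of the unchanged genes were counted too. That share may be raised by real effects contained in the spread used, but 1 array per arm cannot separate them from scatter. Both of 2 lists shifted by 0.6 stood apart, and 0 of 29 unshifted lists did. Alternatives were another level filter, a floor, median, quantile and lowess centring of the 2 arrays, the mean of a gene's probe sets, other fold thresholds, unmatched random lists and the mean in place of the median. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, statsmodels 0.14.6 (lowess, fraction 0.3) and matplotlib 3.10.9 were used.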

Results

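Expression was profiled in UM-PEL-1 lymphoma cells recovered from the peritoneal cavity of mice 24 hours after a single dose of bortezomib (0.3 mg/kg) or of PBS. Each arm consisted of 1 pool of RNA from 3 mice hybridised to 1 human gene array, so values below have no replicate error. Differences are bortezomib minus PBS on the log2 scale of the deposited values. Folds are given as a description of these 2 pools. Values correlated across probe sets between the arrays (Pearson r = 0.96, across probe sets, which are not independent replicates). Different probe sets of one gene, present for 373 genes past the level filter, differed with an SD of 0.44. A difference smaller than that cannot be told from scatter between probe sets. It is 1 SD over all levels, so a larger difference is not thereby resolved.

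The comparison asked which transcripts differed in the lymphoma cells after proteasome inhibition in vivo. Lists of genes of the proteasome, of the ATF4 and NRF2 stress programmes and of the endoplasmic reticulum (ER) chaperone system had higher medians in the bortezomib pool, as did a short list of ubiquitin genes and shuttle factors whose members were split. Genes of ribosome biogenesis, MYC-activated genes, DNA replication genes and, less stably, glycolysis genes were lower. Of 11222 genes past the level filter, 428 (3.81%) were at least 2-fold higher and 1188 (10.6%) at least 2-fold lower. In the simulation, 8.30% of unchanged genes past the filter were counted as well, so an unknown part of these counts can be scatter. Of the genes that differed 2-fold, 26.5% were higher with the values as deposited. After lowess centring on mean level, 570 were higher and 810 lower, which put the higher share at 41.3%. The median difference was 0.03 over all named genes but depended on level: it was -0.37 in the eighth level decile and 0.01 in the tenth.

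**Figure D1:**
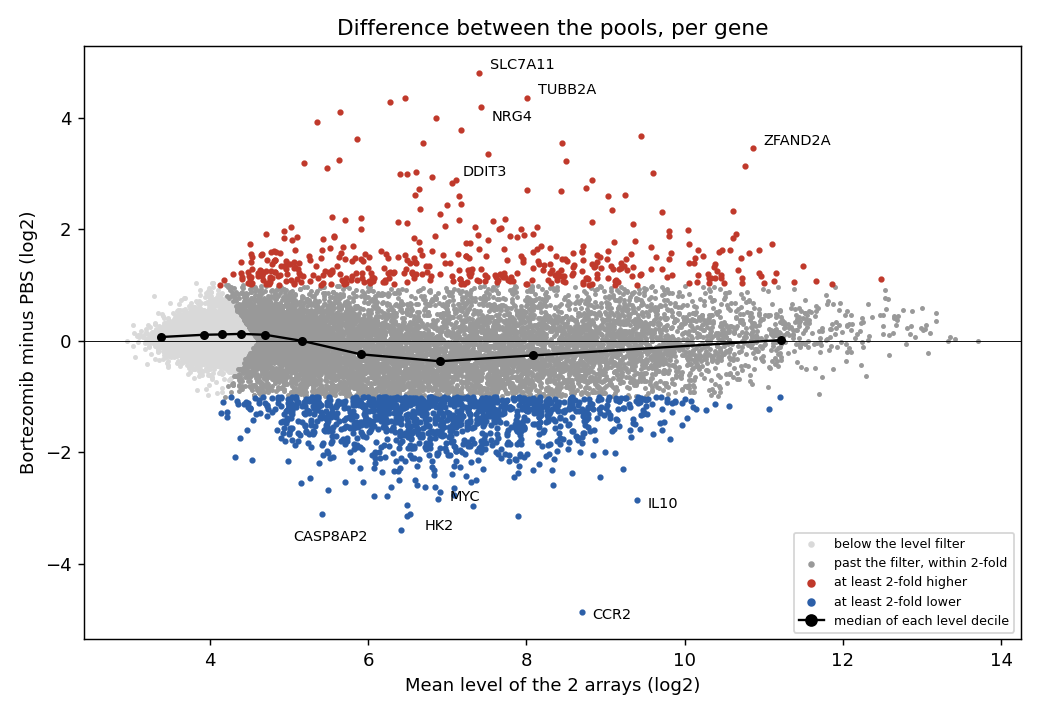
Difference between the bortezomib and PBS pools (log2, vertical axis) against the mean level of both arrays (log2, horizontal axis), 1 point per gene. Red and blue points are the 428 genes at least 2-fold higher and the 1188 at least 2-fold lower past the level filter, and the black line joins the median difference of each level decile, which dips to -0.37 at intermediate levels.

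The highest difference was that of SLC7A11, the cystine-glutamate exchanger, which measured 9.80 with bortezomib, a difference of 4.80 from PBS or 27.9-fold. TUBB2A, a beta-tubulin, was 20.4-fold higher (5.83 and 10.2), and its difference of 4.35 became 3.51 when its 3 probe sets were averaged. NRG4, a ligand of the epidermal growth factor family, was 18.3-fold higher, ZFAND2A, a proteasome-associated protein known to respond to arsenite, 10.9-fold, and TEX14, a germ cell gene, 9.41-fold. The other 10 of the 15 highest differences were small non-coding RNAs, among them the spliceosomal RNA variants RNVU1-6 (20.5-fold), RNVU1-3 (19.4-fold) and RNVU1-4 (12.7-fold). These variants are near-identical copies. Signal may be split among them or shared by them, so they are not separate measurements. SCARNA14 was 17.1-fold, SNORA38B 16.0-fold, RNY1 15.2-fold, SNORA62 13.7-fold, SCARNA22 11.7-fold, SNORA67 11.6-fold and RNU4ATAC 10.2-fold higher. The PBS values of RNVU1-6 (4.28), RNVU1-3 (4.13), TEX14 (4.01), SCARNA14 (3.59) and RNY1 (3.39) lay below the level filter. With the floor, the differences of RNY1 and SCARNA14, 3.93 and 4.10, became 3.34 and 3.71. With small RNAs set aside, a step chosen after the data were seen, the 15 highest also held DDIT3 (7.13-fold), the cysteine-forming enzyme CTH (5.42-fold), GADD45A (4.56-fold), PHF1 (5.14-fold), BLOC1S2 (5.05-fold), CAMK2G (4.60-fold), POPDC3 (5.49-fold), FAM209B (9.07-fold), the pseudogene UBE2Q2P1 (6.09-fold) and the mitochondrial-sequence pseudogene MTND2P28 (4.99-fold). The PBS value of FAM209B (3.59) lay below the level filter and below the floor of 3.97.

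The lowest difference was that of CCR2, a chemokine receptor, which measured 11.1 with PBS and 6.26 with bortezomib, 29.2-fold lower. CASP8AP2, a factor in histone transcript processing, was 10.5-fold lower, WDR3, a ribosome assembly protein, 8.83-fold, FAM111B 8.78-fold and HK2, a hexokinase, 8.60-fold. IL10, a cytokine known as a growth factor of primary effusion lymphoma cells, was 7.26-fold lower (10.8 and 7.97). The transcription factors MYC (8.30 and 5.47) and MYB (8.27 and 5.56) were 7.11-fold and 6.54-fold lower. The remainder of the 15 lowest were LINC01560 (8.56-fold), SCFD2 (7.76-fold), TRIM48 (7.68-fold), ENOX2 (6.87-fold), GPD2 (6.84-fold), CCP110 (6.80-fold) and PIGM (6.36-fold).

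Proteasome genes, the drug's target complex, were higher as a group. Of 38 measured subunit and assembly genes, 33 were above 0, 7 were at least 2-fold higher and 0 were 2-fold lower. Their median difference was 0.56 (1.47-fold, quartiles 0.40 and 0.91), above all 10000 matched random lists. The regulatory-particle subunits PSMD12 (3.02-fold), PSMD11 (2.38-fold), PSMD3 (2.31-fold) and PSMD2 (2.14-fold) led the list. PSMB5, the catalytic subunit that bortezomib binds, differed by 0.39 (1.31-fold), within the scatter of probe sets, and PSMD5, an assembly chaperone, by -0.67. The immunoproteasome and antigen presentation list had a median of -0.20 over 13 genes (percentile 29.3), with TAP1, a peptide transporter, 2.15-fold lower. PSMB9 at -0.49, ERAP1 at -0.48 and PSMB10 at -0.44 lay within or near the scatter of probe sets. CALR differed by 0.22 (-0.12 after quantile normalization).

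Ubiquitin genes and shuttle factors had a median of 0.66 over 15 measured genes, above all random lists, with 4 at least 2-fold higher and 0 lower. The list was mixed, with 9 genes above 0 and 6 below, a lower quartile of -0.35 and a bootstrap standard error over genes of 0.42. ZFAND2A and its relative ZFAND5 (2.04-fold) were higher, as were NPLOC4 (4.05-fold) and UFD1 (2.33-fold), the cofactors that direct the VCP segregase to ubiquitylated proteins. UBQLN2 differed by -0.64. Among 20 autophagy and lysosome genes past the filter, ATG12 (2.77-fold) and MAP1LC3B (2.12-fold) were at least 2-fold higher and 18 were within 2-fold. ATP6V1H differed by 0.74, LAMP2 by 0.50 and BNIP3L by -0.75, and the list did not stand apart (median 0.06, percentile 88.4).

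Targets of ATF4, the transcription factor of the integrated stress response, had a median of 0.70 over 30 measured genes (quartiles 0.16 and 1.24), above all random lists. The median of the 25 past the filter was 1.07, and 13 were at least 2-fold higher and 1 was lower. SLC7A11, DDIT3 (5.64 with PBS and 8.47 with bortezomib), CTH and ATF4 itself (3.20-fold) were the highest. ATF3, a stress-induced factor, differed by 1.16 from a PBS value of 4.07 below the level filter. The one lower was AARS1, a transfer RNA synthetase (3.40-fold). ER chaperones and degradation factors had a median of 0.33 over 23 genes (percentile 99.7), with 3 at least 2-fold higher and 0 lower. These were HERPUD1 (3.23-fold), which serves ER-associated degradation, DNAJC3 (2.43-fold) and SEC24D (a difference of 1.14). HSPA5, the main ER chaperone, was 1.88-fold higher, XBP1 differed by 0.13 and OSTC by -0.60.

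Antioxidant genes of the NRF2 programme had a median of 0.47 over 22 measured genes, above all random lists, and 5 of 17 past the filter were at least 2-fold higher and 0 lower. SQSTM1, an autophagy receptor, was 2.91-fold higher, HMOX1, heme oxygenase, 2.31-fold, NQO1 2.29-fold and GCLM, of glutathione synthesis, 2.07-fold. MAFG was 2.64-fold higher by its brightest probe set but differed by only 0.47 when its 3 probe sets were averaged. Its PBS value by the brightest probe set, 4.42, lay below the level filter. TKT, of the pentose phosphate pathway, went the other way (-0.99). The list of metallothioneins and the zinc exporter SLC30A1 had a median of 0.34 over 10 genes (percentile 99.4, short of the limit). It was 0.21 with probe sets averaged (percentile 95.0), and the mean was 0.15 (percentile 92.9). None was 2-fold higher (0 genes): MT1F differed by 0.60, MT1M by 0.55, MT1G by 0.45 and MT1H by 0.44. MT1M started from 4.39 with PBS, below the level filter. The metallothioneins are near-identical family members. SLC30A1 was 2.62-fold lower.

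The cytosolic heat shock list did not stand apart (median 0.08 over 24 measured genes, percentile 74.2). HSPA1A and HSPA1B, which share their probe sets, are not among the measured genes, so the list says nothing of them. Of 20 genes past the filter, 3 were at least 2-fold higher, namely the co-chaperones BAG3 (2.74-fold) and DNAJB4 (2.49-fold) and the small heat shock protein CRYAB (2.22-fold, from 3.83 to 4.98). HSPB1 differed by 0.92 and DNAJB1 by 0.77. FKBP4 was 2.12-fold and HSPA4L 2.08-fold lower. The median was -0.01 after quantile normalization and 0.29 with the level filter (percentile 98.6), and the mean was 0.23 (percentile 97.9), none of them past the limit.

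Ribosome biogenesis genes had the lowest list median, -0.99 over 30 genes (1.98-fold lower, quartiles -1.21 and -0.22), below all random lists. Of these, 15 were at least 2-fold lower and 0 higher. NOC3L (5.14-fold), DDX10 (a difference of -2.32), WDR12 (4.91-fold) and LYAR (4.39-fold), which act in assembly or transcription of ribosomal RNA, were the lowest, and TAF1D differed by 0.35. MYC and MYC-activated genes had a median of -0.65 over 31 genes (percentile 0.02), with 6 at least 2-fold lower and 0 higher. Several members of this list, RRP9 among them, also act in ribosome biogenesis, so it is not independent of the list above. Besides MYC itself, PPAT, of purine synthesis, was 5.41-fold lower, the cell cycle kinase CDK4 3.43-fold and RRP9 3.27-fold, while IARS1 differed by 0.49. Cytosolic ribosomal protein genes differed from this: 27 of 36 were above 0, none passed 2-fold (0 higher, 0 lower) and the median was 0.14 (percentile 89.4). That direction was lost on rescaling, with a median of -0.07 after quantile normalization and -0.11 after lowess centring. RPL32 differed by 0.90, RPS20 by 0.77, RPL10A by 0.67, RPS27 by 0.47 and RPS9 by -0.24. Small nucleolar, Cajal body and spliceosomal RNAs, a class taken after the data were seen, had a median difference of 1.10 over 146 genes past the filter, with 80 at least 2-fold higher and 2 lower.

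DNA replication genes were lower as a group, with a median of -0.77 over 48 measured genes (1.71-fold lower, quartiles -1.12 and -0.37), below all random lists. Of 47 past the filter, 17 were at least 2-fold lower and 1 was higher. The cyclins CCNE2 (3.63-fold) and CCNE1 (3.62-fold), which drive entry into S phase, and the helicase components GINS1 (3.48-fold) and MCM3 (3.34-fold) were lowest. ORC1, an origin recognition subunit, was 2.32-fold higher. Mitotic genes had a median of -0.33 over 42 genes (percentile 1.5), or -0.16 after lowess centring, and did not stand apart by the rule, with 6 at least 2-fold lower and 0 higher. TOP2A (3.20-fold), BUB1 (2.99-fold), SPC25 (2.57-fold) and KIF4A (2.09-fold) were lower, TTK differed by 0.97, CCNB1 by -0.30 and the proliferation marker MKI67 by -0.27. Histone genes went both ways (median -0.06, percentile 67.1, and 0.02 after lowess centring), with 5 of 27 past the filter at least 2-fold lower and 1 higher. H2BC14 (3.14-fold), H2BC7 (2.93-fold), H4C4 (2.52-fold), H3C8 (2.45-fold) and H3C10 (2.17-fold) were lower and H2BC4 2.05-fold higher, with the reservation that histone genes are near-identical in sequence.

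Targets of p53 did not differ as a group (median -0.04 over 29 genes, percentile 49.0, and -0.16 with the level filter), with 1 at least 2-fold higher and 3 lower. The one higher was GADD45A, a growth arrest gene also known to respond to stress. The death effector BAX (2.96-fold), the death receptor FAS (2.60-fold) and SESN1 (2.54-fold) were lower. ZMAT3 differed by -0.67, CDKN1A, the cell cycle inhibitor p21, by -0.47 and MDM2 by -0.34. With bortezomib, ZMAT3 (4.36) and CDKN1A (4.30) lay below the level filter. Among pro-apoptotic genes, 1 was at least 2-fold higher and 4 were lower (median 0.10, percentile 92.5). TNFSF10, the death ligand TRAIL, was 3.50-fold higher. Besides BAX and FAS, the lower genes were APAF1, the apoptosome scaffold (2.19-fold), and the TRAIL receptor gene TNFRSF10A (2.26-fold). Its relative TNFRSF10B, BMF and PMAIP1 each differed by 0.86, BMF from a PBS value of 4.03 below the level filter. The mean of this list was -0.01, of opposite sign to its median. Anti-apoptotic genes had a median of -0.37 over 10 genes (percentile 2.95) and a mean of -0.23 (percentile 21.2), with 0 past 2-fold. MCL1 differed by -0.85, XIAP by -0.62, TNFAIP8 by -0.54, CFLAR by -0.37 and BCL2L1 by 0.49, and BCL2 stayed below the level filter on both arrays (4.28 and 4.01).

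NF-kappa-B targets did not stand apart (median 0.07 over 32 genes, percentile 71.5, and -0.02 after quantile normalization). CCL5, a chemokine, was 2.55-fold higher and CCR7, a chemokine receptor, 2.90-fold lower. REL differed by 0.95, the inhibitor NFKBIA by 0.89 and RELB by 0.79. With PBS, RELB (4.54) and CCL5 (4.27) lay below the level filter. IL6 stayed below the level filter (4.41 and 4.48). The interferon list had a median of -0.05 (percentile 9.90), which was 0.02 after lowess centring, and a mean of 0.03. OAS2 was 2.72-fold lower, IFI44 2.38-fold and IFIT5 2.07-fold higher, with EPSTI1 at -0.89, IFI35 at -0.42 and SAMD9L at -0.34. IFI44 started from a PBS value of 4.15, below the level filter. Immediate early genes had a median of 0.18 (percentile 97.0), or 0.29 with the level filter (percentile 99.0), with 0 past 2-fold, among them JUN at 0.81, JUND at 0.53, FOS and DUSP1 at 0.43 each and KLF2 at -0.88.

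Glycolysis and hypoxia genes had a median of -0.41 over 24 genes (percentile 0.29), with 4 of 21 past the filter at least 2-fold lower and 0 higher. HK2, ANKRD37 (2.69-fold), the glucose carrier SLC2A1 (2.42-fold) and the collagen hydroxylase P4HA1 (2.27-fold) made up the 4. SLC2A3 differed by 0.71, from a PBS value of 3.97 below the level filter, and VEGFA by -0.43. The list no longer stood apart after lowess centring (-0.24, percentile 2.24) or quantile normalization (-0.33, percentile 1.70). Respiratory chain genes were within 2-fold (28 of 28, median 0.11, percentile 85.2, and -0.02 after quantile normalization), with COX4I1 at 0.74, COX6C at 0.55, NDUFS3 at 0.53, NDUFA1 at 0.43 and SDHA at -0.66. Cholesterol synthesis genes were split (median -0.22, percentile 37.7, and -0.05 after lowess centring). SQLE was 3.61-fold and INSIG1 2.34-fold lower, IDI1 was 2.86-fold higher, EBP differed by -0.92 and DHCR7 by -0.86.

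Plasma cell and primary effusion lymphoma markers had a median of -0.30 over 23 genes (percentile 7.77), with 5 of 21 past the filter at least 2-fold lower and 0 higher. Besides IL10, these were the selectin ligand SELPLG (4.64-fold), the plasma cell regulators PRDM1 (2.74-fold) and IRF4 (2.14-fold), and the coactivator POU2AF1 (2.14-fold). EAF2 differed by 0.28. The mean of the list, -0.55, stood apart (percentile 0.19), whereas its median did not. B cell identity genes had a median of -0.01 (percentile 15.7) with 0 past 2-fold. The median was 0.19 with the level filter (percentile 76.9) and -0.12 after lowess centring. Values were SYK at -0.95, CIITA at -0.58 and CD79A at 0.66, the last from a PBS value of 4.43 below the level filter.

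Markers of other cell types stayed low on both arrays for the most part. The array lists human genes and the host cells are of the mouse, so low values do not measure how many host cells were present. Among macrophage markers 4 of 19 passed the level filter, and the list median was 0.21 (percentile 97.3), or 0.09 after lowess centring, with CD14 at 4.04 and 5.02 and CD68 at 4.63 and 5.29. TYROBP differed by -0.39 and SIGLEC1 by 0.06, or -0.05 after quantile normalization or lowess centring. Erythroid markers had a median of 0.27 over 8 genes (percentile 98.1), or 0.18 after lowess centring, with HBB at 5.15 and 5.86, HBD at a difference of 0.54 and KLF1 at 4.79 and 5.07. Mesothelial and fibroblast markers had a median of 0.19 (percentile 90.7) and a mean of 0.07, with COL1A1 at 0.42, LRRN4 at 0.38, COL1A2 at 0.37, COL6A1 at 0.23 and ACTA2 2.03-fold lower. Neutrophil and mast cell markers had a median of 0.08 (percentile 45.2), with S100A9 at 0.63, MMP9 at 0.36, LTF at 0.27 and ELANE at -0.11. Of T and NK cell markers, 6 of 18 passed the filter (median 0.05, percentile 35.7, and -0.01 after quantile normalization and -0.02 after lowess centring). GZMA, a cytotoxic granule protease, was abundant on both arrays (12.4 and 12.9), CD7 differed by 0.31 and TRAT1 by -0.54. None of these lists stood apart.

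**Figure D2:**
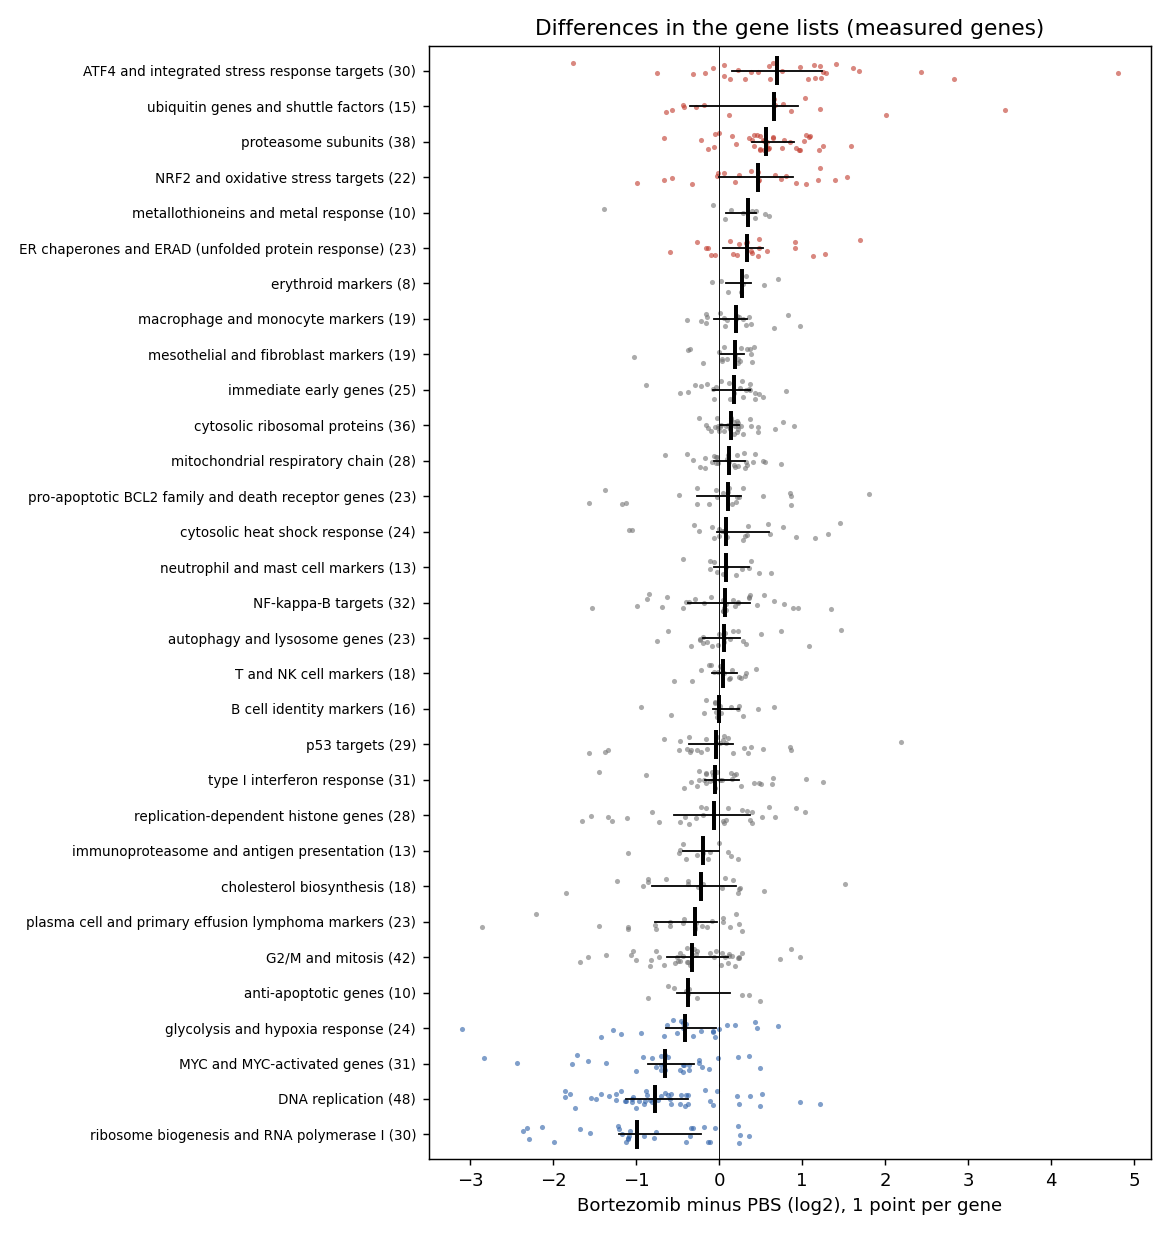
Difference between the bortezomib and PBS pools (log2, horizontal axis) for each measured gene of the 31 lists, ordered by list median, with the number of genes measured in brackets. Thick bars are medians and thin lines quartiles, and colour marks the 5 lists that stood apart higher (red) and the 4 that stood apart lower (blue), from 0.70 for ATF4 targets to -0.99 for ribosome biogenesis.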

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

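The tests of short-RNA recovery, of host transcripts and of tumour cell share were chosen after values they measure had been seen. The lowess and quantile tests were fixed before their results but after the differences per gene and per level decile had been seen. The host test was split by whether a host was assigned, after its ratio had been seen. The tumour share test was first run against the least lowered list alone, was undecided, was split by list after that, and was then repeated on list means. All 3 patterns below were found in and tested on the same 2 arrays, and the treatment itself, as the biological explanation, is confounded with the single pool per arm. Of the probe sets outside the report, 122 of 1146 past the level filter that carry several gene symbols were at least 2-fold higher with bortezomib, and 52 lower. Of 2789 past the filter that are not listed with a gene, 360 were at least 2-fold higher and 123 lower. The shares higher were 10.6% and 12.9%, against 3.81% of named genes.

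Small nucleolar, Cajal body and spliceosomal RNAs were higher with bortezomib, 126 of 146 being above 0. A shift shared by all probe sets of their level would have vanished on lowess centring, but the class median was then 1.22 (bootstrap standard error over genes 0.13). That standard error may be too low, because near-identical copies can share signal. For the 26 RNAs with an assigned host, which lean to the largest differences, a parallel increase of the 15 host transcripts is argued against: the ratio of host to RNA difference was -0.0027 (standard error 0.11), and no host exceeded 0.77. It stays open for other RNAs in introns, since only 17.8% of the class had a host value, and it does not apply to spliceosomal RNAs, which have promoters of their own. Altered recovery or amplification of short RNA between the pools stays open: ribosomal protein transcripts, which are short messenger RNAs, had a median of 0.14 as deposited and -0.11 after lowess centring, and a gain of very short RNA need not reach them.

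More genes were 2-fold lower than higher, 2.78 lower for each higher. The ratio was 1.42 after lowess centring, but that centring pulls it toward balance whatever the cause, so a level-dependent shift left by the normalization and a real effect on genes of intermediate level both stay open. Quantile normalization gave 1.90, between the bounds set for and against unequal distributions, so that explanation stays open too.

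Ribosome biogenesis, MYC-activated and DNA replication genes were lower together. The MYC list is not independent of the ribosome biogenesis list, since several of its members also act in that process. A level-dependent shift is argued against, because the least lowered of the 3 list medians was still -0.52 (bootstrap standard error 0.08) after lowess centring. A lower share of tumour cells would lower tumour markers about as much. By medians they lay 0.69 (standard error 0.28) above ribosome biogenesis, 0.48 (0.18) above DNA replication and 0.36 (0.18) above the MYC list, but by means only 0.34 (0.22), 0.13 (0.19) and 0.16 (0.21), so this explanation stays open for all 3. The treatment stays open too, untested.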

How the results depend on the processing

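The removal of small RNA genes was chosen after the data were seen. No paired analysis was possible because each arm has 1 array, and for the same reason no array could be left out. The counts of 428 higher and 1188 lower genes stayed within 1.5-fold under the other level filters, the floor, the 3 other scalings, the averaging of probe sets and the removal of small RNA genes. Of the called genes, 406 higher and 792 lower were shared with the lowess-centred counts. A threshold of 1.5-fold gave 1200 higher and 2552 lower genes, and 4-fold gave 61 and 107, as the change of threshold implies. Of the 9 lists that stood apart, 8 did so under every alternative run. Glycolysis and hypoxia was the exception: its median of -0.41 no longer stood apart at -0.33 after quantile normalization, -0.24 after lowess centring and -0.44 with the level filter (percentile 2.01), and the cause was not tested. With unmatched random lists, mitosis (-0.33, percentile 0) and plasma cell markers (-0.30, percentile 0.40) stood apart, because matching on level had been dropped, and the latter also by its mean of -0.55. Of 203 named genes, those at least 2-fold different kept their direction under the 5 alternatives run on genes. Values moved by more than 0.44 for TUBB2A, MAFG, RNY1 (3.93, and 3.34 with the floor) and SNORD13P2 (-2.09, and -1.39 with the floor). The level filter gave no value for 5 lists with fewer than 8 members past it. Level limits what can be said of genes near background: in the lowest level decile the SD of differences was 0.18, against 0.86 in the eighth.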

Other observations

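All families in this part were taken by symbol after the data were seen. Of 35 scanned, 31 had at least 8 genes past the level filter and 5 stood apart from random lists by the same rule. These were the 4 families of small RNAs below and the proteasome symbols, which repeat a list of the report. Spliceosomal small nuclear RNAs had the highest median, 2.79 over 16 genes, with 15 at least 2-fold higher. Near-identical copies among them can share signal, so the 15 are not separate measurements. Cajal body RNAs, which guide modification of spliceosomal RNAs, had a median of 1.70 over 14 genes, with 11 at least 2-fold higher. The C/D box small nucleolar RNAs, guides of ribosomal RNA methylation, had a median of 0.92 over 74 genes (34 higher, with SNORD4B and SNORD13P2 the 2 lower), and the H/ACA box RNAs, guides of pseudouridylation, 0.94 over 42 genes (20 higher, 0 lower).

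Zinc finger genes, a large family of transcriptional repressors and activators, had a median of -0.15 over 336 genes (percentile 0.71). After lowess centring the median was -0.10 at percentile 0.07, past the limit. At least 2-fold lower were 34 and higher 15, near the shares over all genes past the filter (10.6% lower and 3.81% higher). Tubulins did not share the difference of TUBB2A: the family median was 0.09 over 16 genes, with TUBA1C (1.22) the other one 2-fold higher and TUBD1 (-1.52) the one lower. Solute carriers did not stand apart (median -0.11 over 219 genes, percentile 12.5), with 28 at least 2-fold lower and 2 higher. The 2 higher were SLC7A11 and its partner chain SLC3A2 (1.25). The wider ubiquitin families did not stand apart. Ubiquitin-conjugating enzymes had a median of -0.09 (percentile 66.6, and 0.01 after lowess centring), ubiquitin-specific proteases -0.22 (percentile 30.2, and 0.06 after lowess centring) and RING finger genes -0.02 (percentile 91.4, and 0.07 after lowess centring). Aminoacyl-tRNA synthetases had a median of -0.02 over 19 genes, with GARS1 (1.14) the 1 higher and AARS1 (-1.76) and FARSA (-1.48) the 2 lower.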
